A study of Homo sapiens with 8 samples.

How the data were processed

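RNA was sequenced from H1703 cells, an established line of human lung squamous cell carcinoma, in 4 groups of 2 libraries each. Cells with a knockdown of SPIB were compared with control cells that carried a knockdown of luciferase, and both were taken attached or floating, which is called detached here. Per the labels' protocols, total RNA was taken with Trizol and complementary DNA was made with a first strand synthesis kit. The sequence of the knockdown reagent is not given in the sources used here, nor is the strandedness of the libraries or the gene annotation.

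The authors deposited FPKM values, fragments per kilobase of transcript per 1000000 mapped fragments, in a separate table for each library. Per the submitters' processing notes, HISAT, Cuffnorm and genome build hg19 were used. Their versions are not given in the sources used here. The tables list the same 28590 loci with hg19 positions. Of these, 1673 have no gene symbol and 1961 merge the symbols of several genes into 1 locus, whose value cannot be split among them. Loci of the same symbol were summed, which added 1386 loci to others and left 27204. The 53 loci listed at 0 in a library and at 10 FPKM or more in another were kept, since a 0 from such an estimate can be a failed one, and 21 of them were tested.

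FPKM values hold no read totals. The sums of FPKM per library lay between 707883 and 786285. The most frequent ratio of low values between libraries, taken in bins of 0.002 on the log2 scale, gives what 1 read is worth in each library. By this measure the deepest library had 1.60 times the reads of the shallowest. Deeper libraries measure low genes with less error, and the absolute depth is unknown.

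Values were taken as log2(FPKM + 1), which understates the change of genes with low values. A gene was tested if FPKM reached at least 1 in at least 2 of the 8 libraries, which left 13438 genes and loci, 1642 of them (12.2%) merged loci and 333 without a symbol. limma (lmFit, contrasts.fit and eBayes with an intensity trend) was fitted to all 8 libraries with 1 mean per group, so that all groups share 1 estimate of the spread with 4 residual and 3.42 prior degrees of freedom. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were detachment in control cells, SPIB knockdown in detached cells, SPIB knockdown in attached cells, detachment in SPIB-knockdown cells, and the interaction, which is the knockdown effect in detached cells minus that in attached cells. "Rose" and "fell" are used of genes that passed this test, and of lists that passed the test described next. Each log2 fold change is given with its standard error (SE), and each mean FPKM with its SD over 2 libraries.

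A set of 32 gene lists, the contrasts, the filters, the rule for named genes and most of the alternatives were fixed before the data were examined. List members that lie only in merged loci were left out. Lists were tested against all other tested genes with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over 160 tests (32 lists in 5 contrasts). camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction, were run beside it. With an estimated correlation the smallest adjusted p was 0.328, so none of the 38 calls held. By fry, 26 of these 38 had an adjusted p under 0.05. On simulated data a list of 17 genes planted at 0.3 log2 in the comparison of attached cells had an adjusted p of 2.03e-21 by camera, 0.0851 with an estimated correlation and 0.0119 by fry.

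The named genes were, for each pairwise contrast, the 8 with the largest and the 8 with the smallest log2 fold change among called genes that moved the same way in all pairs of libraries across both groups, leaving out symbols that start with LOC, LINC, MIR, SNOR, SCARNA, RNU, RNA5, RN7, RPL, RPS or MT-, that hold -AS, or that end in P and a digit. The last pattern, meant for pseudogenes, also left out IGFBP3 and MMP1, and MMP1 came in as a list member. Loci with a clone name or no symbol passed the rule and count among the named calls. Up to 4 members with the smallest p were added from each list that passed its test or held called genes, as were SPIB, SNAP47, MAP1LC3B, SQSTM1, LAMP1 and CTSB. IGFBP3, called genes shared between contrasts, further called members of lists, carriers of a short 3′ UTR word and host genes of small nucleolar RNAs lie outside this rule and were chosen after their values were seen. Loci with a clone name or without a symbol are given no fold change. Most loci listed near 0 in a group are given none either, but some below 1 FPKM in a group are, such as STC1 and KRTAP2-4. Some genes that meet the rule are not reported here.

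Correlations of fold changes between contrasts are across genes, which are not independent replicates, and carry no p. For the pair of contrasts that share the detached control libraries, 1000 simulations of unchanged groups gave the correlation and covariance that the shared libraries produce. The overlap of independent lists is n1 × n2 / N.

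After the results were seen, all 16305 words of 7 bases found in the 3′ UTRs of at least 30 genes were scanned for association with each fold change, in a model with 3′ UTR length, base composition and mean expression. The longest annotated 3′ UTR of each gene was taken from a GRCh38 annotation, by symbol. 9688 of the tested genes (72.1%) had one, including 82.7% of those lowered by knockdown in attached cells and 84.3% in detached cells. A set of 100 permutations of the fold changes by knockdown in attached cells, after this model, gave a largest absolute z of 5.35. No permutations were run for the other contrasts. The words followed below were picked by their z in attached cells. hg19 coordinates come from the deposited tables and GRCh38 coordinates from this annotation, with no conversion between the builds.

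The alternatives were a pseudocount of 0.1, no filter on low values, a filter at 5 FPKM, median of ratios scaling, quantile normalization, rescaling to 1000000 after removal of small RNA, rRNA and mitochondrial genes, the replicate number as a block, only the 4 libraries of the groups compared, no intensity trend, and each library left out in turn. Without a library its group has 1 sample, which is assumed to vary like the others. Further alternatives were chosen after seeing the data. They leave out loci listed at 0 in a library and at 10 or more in another, leave out loci that merge several genes, and leave out each library in turn for the gene lists.

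The limma fit was tested on simulated data of 13438 genes. Changes were planted only in genes with a mean log2(FPKM + 1) above 2, so the shares below do not cover lower genes. It recovered 47.8%, 88.1% and 97.0% of genes changed by 0.5, 1 and 2 log2 for detachment in control cells, with 5 unchanged genes called. For knockdown in detached cells it recovered 53.7%, 89.6% and 97.0%, with 5 unchanged genes called. For knockdown in attached cells the shares were 49.3%, 89.6% and 97.0%, with 13 unchanged genes called, and for detachment in knockdown cells 49.3%, 74.6% and 100%, with 8. Software was R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.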

Results

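RNA levels were measured by sequencing in H1703 cells, a human lung squamous cell carcinoma line. The question, as far as the series title gives it, concerned the transcription factor SPIB, resistance to anoikis and the autolysosomal process. SPIB is an ETS family factor best known from B lymphocytes. Anoikis is the cell death that follows loss of attachment to the extracellular matrix. Cells with a SPIB knockdown and control cells with a luciferase knockdown were each taken attached or detached. Each of the 4 groups has 2 libraries. The labels call these biological repeats, and the p-values measure the spread between these samples. A treatment note of 12 hours of floating stands in the labels of all 8 samples, the attached ones included.

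FPKM summed to 732916 and 776025 in the attached control libraries and to 786285 and 743467 in the attached knockdown libraries. The sums were 708338 and 751541 in the detached control libraries and 707883 and 753925 in the detached knockdown libraries. Between 13022 and 13283 loci reached 1 FPKM. Relative to attached control replicate 1, the read depth of the other libraries, estimated from low values, lay between 0.79 and 1.26. Replicates of a group differed by a median of 0.10 to 0.11 log2 over the tested genes. Their Spearman correlation across genes lay between 0.987 and 0.989. Without loci listed at 0 in a library and at 10 FPKM or more in another, all 4 detached libraries lay apart from all 4 attached ones along the first principal component (28.8% of the variance). The next component, with 17.8%, placed all 4 knockdown libraries below all 4 control libraries. Over all 13438 tested genes the first component (24.7%) still parted attached from detached libraries. The second (20.2%) set the replicates of each group apart and did not separate knockdown from control. Its positive side held the 4 libraries in which a mitochondrial locus is listed at 0. These libraries also had the lower FPKM sum of their group.

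**Figure D1:**
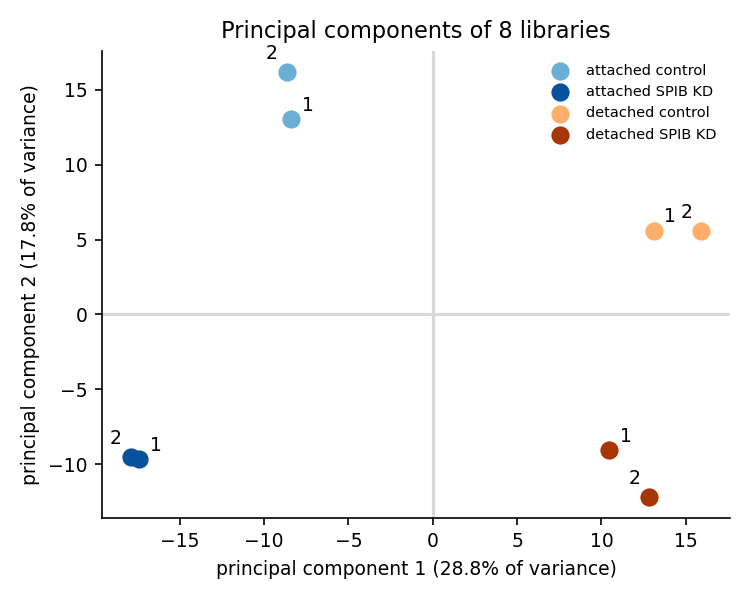
Each point is 1 of the 8 libraries, placed by its scores on the first (x axis, 28.8% of the variance) and second (y axis, 17.8%) principal components of log2(FPKM + 1) over 13417 genes, without the loci listed at 0 in a library and at 10 FPKM or more in another. Detached libraries lie to the right of attached ones, and SPIB-knockdown libraries lie below control libraries.

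SPIB itself is listed only inside a locus that merges it with POLD1, a DNA polymerase subunit gene, and CTD-2545M3.6 (XLOC_025378, chromosome 19, 50887346 to 50934570, hg19). FPKM of this locus was 55.9 and 51.2 in the attached control libraries and 47.5 and 52.5 in the attached knockdown libraries. It was 44.9 and 49.8 in the detached control libraries and 41.8 and 44.3 in the detached knockdown libraries. The log2 fold change by knockdown was −0.10 ± 0.08 in attached cells (limma, adjusted p = 0.594) and −0.13 ± 0.08 in detached cells (adjusted p = 0.574), and neither passed the test. Since the share of SPIB in this value cannot be separated, the knockdown could not be checked from these values, and groups are named by their labels.

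**Figure D2:**
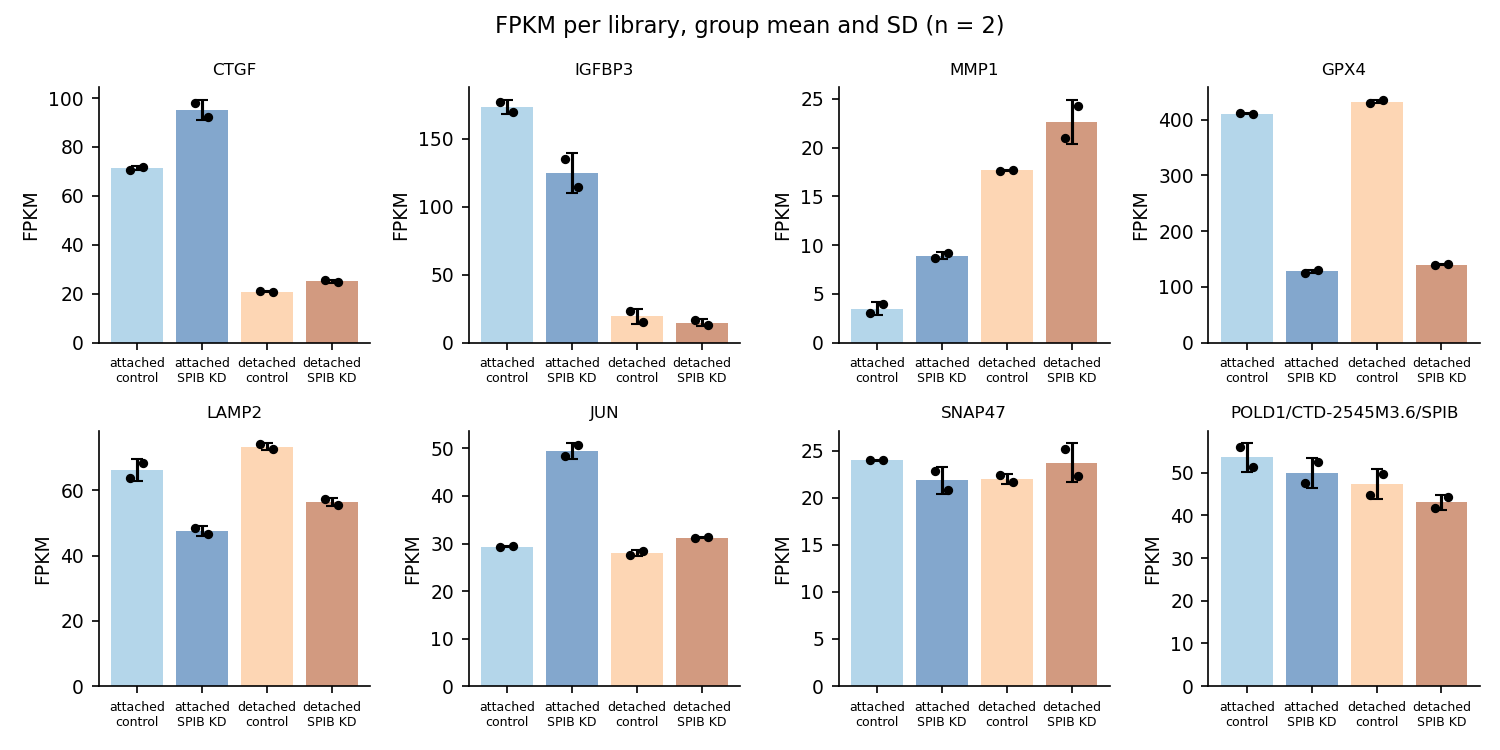
FPKM (y axis, from 0) of 7 genes and of the locus that holds SPIB in the 4 groups (x axis). Bars are means, error bars are SD with n = 2 and points are single libraries, and GPX4 lies near 420 FPKM in both control groups and near 130 FPKM in both knockdown groups.

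Detachment of control cells, which asks what loss of attachment changed without the SPIB knockdown, lowered CTGF, CYR61 and AMOTL2, which are targets of the coactivator YAP. CTGF, a matricellular growth factor, fell from 71.3 ± 0.833 to 20.8 ± 0.274 FPKM (SD, n = 2, 3.32-fold on FPKM + 1, log2 fold change −1.73 ± 0.05, adjusted p = 4.13e-05, XLOC_044897, chromosome 6, 132269316 to 132272513, hg19). CYR61, its close relative, fell by 1.78 on the log2 scale (adjusted p = 0.000185). AMOTL2, an angiomotin that binds YAP, fell from 79 to 26.7 FPKM. IGFBP3, an insulin-like growth factor binding protein chosen after its values were seen, fell from 174 ± 5.28 to 19.3 ± 5.57 FPKM (log2 fold change −3.13 ± 0.19, chromosome 7, 45951949 to 45961473, hg19). In the other direction MMP1, an interstitial collagenase, rose from 3.47 ± 0.674 to 17.7 ± 0.0274 FPKM (4.20-fold on FPKM + 1, log2 fold change 2.07 ± 0.12, adjusted p = 0.00033, chromosome 11, 102655725 to 102668968, hg19).

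In all, 423 genes changed by detachment in control cells, 120 higher and 303 lower, and 29 of them at least 2-fold, 4 higher and 25 lower. After quantile normalization 159 were higher and 182 lower, and after rescaling without small RNA, rRNA and mitochondrial genes 159 and 187, so the excess of lowered genes depends on the scaling. Groups did not overlap for 51.9% of tested genes, where chance gives 33.3%. Other large decreases were those of KRTAP2-3, a keratin-associated protein gene with a near-identical copy and so uncertain (−2.15 ± 0.13), CCBE1 (−1.84 ± 0.21), the WNT antagonist DKK1 (−1.53 ± 0.23), the transglutaminase TGM2 (−1.38 ± 0.08) and SERTAD4 (−1.38 ± 0.13). Of other increases, NGEF was higher by 1.06 ± 0.11, KLHL24 by 0.94 ± 0.17, the secreted glycoprotein STC1 by 0.88 ± 0.17 and the sulfotransferase SULT2B1 by 0.85 ± 0.12. STC1 lay at only 0.283 and 0.439 FPKM in the attached control libraries, so its value is uncertain. The locus that merges ANG with RNASE4 rose by 0.99 ± 0.15, and its genes cannot be told apart.

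Among YAP and serum response factor targets, of 20 measured members 1 rose and 9 fell, and 2 rose and 11 fell adjusted over the list alone, with a median of −0.20 (adjusted p = 4.94e-06, and adjusted p = 0.328 with an estimated correlation). TPM1, an actin-binding tropomyosin, fell (−0.81 ± 0.07), while VCL, the focal adhesion protein vinculin, rose by 0.24 ± 0.04. Genes of S phase and DNA replication moved down together by smaller amounts, with a median of −0.22, adjusted p = 1.92e-08, and adjusted p = 0.372 with an estimated correlation. Of 35 measured members 2 fell, and 15 fell adjusted over the list alone. TYMS, thymidylate synthase (−0.29 ± 0.04), and RRM2, the ribonucleotide reductase subunit (−0.28 ± 0.05), were those that fell over all genes. Of single genes in lists without a call, the growth arrest gene GADD45A (−1.14 ± 0.06), the chemokine CCL2 (−1.31 ± 0.09), WNT5B (−1.02 ± 0.08) and ETS1 (−0.59 ± 0.04) fell.

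Lysosomal genes rose as a list, with a median of 0.13 and 28 positive values, adjusted p = 0.000453, and adjusted p = 0.328 with an estimated correlation. Of 43 measured members 3 rose, and 4 rose adjusted over the list alone. CTSL, a lysosomal cysteine protease, rose from 174 to 287 FPKM (log2 fold change 0.72 ± 0.04, adjusted p = 0.00033). CTSB rose by 0.34 ± 0.05 and PSAP, the precursor of the saposins, by 0.18 ± 0.03. Among genes of autophagy initiation and autophagosome formation of 36 measured members 2 rose, and 4 rose and 1 fell adjusted over the list alone, with a median of 0.08 (0.13 after quantile normalization and 0.13 after rescaling), adjusted p = 0.0326, and adjusted p = 0.328 with an estimated correlation. The autophagy receptor SQSTM1 rose by 0.29 ± 0.04 and ATG13, a subunit of the ULK1 complex, by 0.41 ± 0.08. This list's call was lost without an intensity trend (adjusted p = 0.0731, range 0.0123 to 0.0731 over its alternatives) and without any 1 of attached control replicate 1 (0.0546), attached control replicate 2 (0.062), detached control replicate 1 (0.0526) and detached control replicate 2 (0.0674). SNAP47, a SNARE protein (−0.12 ± 0.08), MAP1LC3B, which encodes LC3B (0.08 ± 0.07), and LAMP1, a lysosomal membrane protein whose value of −0.01 turns positive under each other scaling, did not pass the test.

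Weaker list calls accompanied these. Hypoxia and glycolysis genes rose, with a median of 0.08 (0.03 to 0.10 with 1 library left out and 0.12 after rescaling), adjusted p = 0.0284, and adjusted p = 0.328 with an estimated correlation. Of 25 measured members 2 rose, and 8 rose and 3 fell adjusted over the list alone, among them NDRG1 (0.63 ± 0.08) and the repressor BHLHE40 (0.48 ± 0.06). Their call was lost without attached control replicate 1 (0.0569), attached control replicate 2 (0.0601) and detached control replicate 2 (0.0941), and with no filter on low values (0.0761) and no trend (0.0781). FOXO and fasting response genes rose, with a median of 0.17, adjusted p = 0.0447, and adjusted p = 0.639 with an estimated correlation. Of 12 measured members 1 rose and 1 fell, and 2 rose and 1 fell adjusted over the list alone, namely KLHL24 and, downward, CITED2. Without attached control replicate 2 (0.156), attached SPIB-knockdown replicate 1 (0.0657), attached SPIB-knockdown replicate 2 (0.0571), detached control replicate 2 (0.12) and detached SPIB-knockdown replicate 2 (0.0523) this call was lost, and so it was with a filter at 5 FPKM (0.153), median of ratios scaling (0.0547) and quantile normalization (0.112). Integrated stress response genes moved down, with a median of −0.13 (−0.15 to −0.07 with 1 library left out and −0.08 after quantile normalization), adjusted p = 0.0326, and adjusted p = 0.7 with an estimated correlation, yet of 28 measured members 2 rose, and 2 rose and 7 fell adjusted over the list alone, and the 2 that rose were the secreted cytokine GDF15 (0.74 ± 0.10) and DDIT4, an inhibitor of mTORC1 (0.43 ± 0.07). Their call was lost without attached control replicate 1 (0.451), attached SPIB-knockdown replicate 1 (0.0538) and detached control replicate 2 (0.257), and with a filter at 5 FPKM (0.0501), quantile normalization (0.244) and no trend (0.0781).

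Epithelial genes moved down, with a median of −0.21 (−0.25 to −0.10 with 1 library left out) that turns to 0.02 after rescaling without small RNA, rRNA and mitochondrial genes, adjusted p = 0.0328, and adjusted p = 0.498 with an estimated correlation. Of 8 measured members 2 fell, and 3 fell adjusted over the list alone, these being the tight junction gene CLDN1 (−1.19 ± 0.07) and the keratin gene KRT18 (−0.75 ± 0.06). The epithelial call was lost without attached control replicate 2 (0.0754), attached SPIB-knockdown replicate 1 (0.0742), attached SPIB-knockdown replicate 2 (0.0655) and detached control replicate 2 (0.0562), and with no filter on low values (0.362), rescaling (0.0629) and no trend (0.0602). Heat shock genes moved down, with a median of −0.10 (−0.06 after quantile normalization and −0.06 after rescaling), adjusted p = 0.0284, and adjusted p = 0.639 with an estimated correlation. Of 13 measured members 1 fell, and 1 rose and 6 fell adjusted over the list alone, the single call being the chaperone HSPA8 (−0.19 ± 0.03). Their call was lost without attached control replicate 1 (0.247) and detached control replicate 2 (0.0834), and with a filter at 5 FPKM (0.0517), quantile normalization (0.214), rescaling (0.0552) and no trend (0.134). Ribosomal protein genes moved down by a median of −0.04 (−0.03 after median of ratios scaling and −0.01 after quantile normalization), which turns to a value just above 0 after the same rescaling, adjusted p = 0.015, and adjusted p = 0.639 with an estimated correlation. Of 42 measured members none passed the limma test over all genes and 6 did at an unadjusted p under 0.05 (over all 13438 tested genes 2761 did), nor did any adjusted over the list alone. This call was lost without attached control replicate 2 (0.0675) and detached control replicate 2 (0.0908), and with a filter at 5 FPKM (0.0718), median of ratios scaling (0.0989), quantile normalization (0.882), rescaling (0.742) and no trend (0.208).

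Leaving out 1 library changed the number of genes called by detachment in control cells by over 1.5 times in each case. It was 72 and 56 without attached control replicates 1 and 2, 91 and 58 without detached control replicates 1 and 2, 270 and 257 without attached knockdown replicates 1 and 2, and 250 and 267 without detached knockdown replicates 1 and 2. Of the 51 named calls, 17 held without each of the 8 libraries. Among them were IGFBP3, KRTAP2-3, CYR61, CTGF, AMOTL2, TGM2, SERTAD4, CCL2, CLDN1, GADD45A, WNT5B, TPM1, KRT18, ETS1, MMP1 and CTSL.

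SPIB knockdown in detached cells, which asks what the knockdown changed once attachment was lost, lowered GPX4 the most among the named genes. GPX4, the selenoprotein that reduces lipid peroxides, fell 3.08-fold, from 432 ± 3.35 to 140 ± 0.476 FPKM (SD, n = 2, log2 fold change −1.62 ± 0.03, adjusted p = 2.01e-06, XLOC_024413, chromosome 19, 1103936 to 1106811, hg19). INA, the neuronal intermediate filament alpha-internexin, fell 2.02-fold, from 161 to 79.6 FPKM (adjusted p = 0.000202). FAM174A (−1.02 ± 0.09), the transcription factor NFE2L3 (−0.99 ± 0.10), SAMD4B (−0.96 ± 0.10) and the cytokine receptor IL27RA (−0.94 ± 0.08) fell by about as much, as did the locus that merges PRAP1 with ZNF511 (−0.98 ± 0.10). The increases were smaller, among them CLDN1 (0.46 ± 0.07) and the asparagine synthetase gene ASNS (0.37 ± 0.04). Of the 99 genes called, 10 rose and 89 fell, 4 of them at least 2-fold and all of these lower.

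Lysosomal genes moved down in detached cells, with a median of −0.06 (−0.10 to −0.04 with 1 library left out), adjusted p = 0.015, and adjusted p = 0.362 with an estimated correlation. Of 43 measured members 2 fell, and 5 fell adjusted over the list alone. LIPA, lysosomal acid lipase, fell from 35.8 to 20.1 FPKM (−0.80 ± 0.10, adjusted p = 0.0187). LAMP2, a lysosomal membrane protein needed for fusion with autophagosomes, fell from 73.5 to 56.4 FPKM (−0.37 ± 0.05, adjusted p = 0.0341). The call of the list was lost without detached control replicate 2 (0.0674) and detached SPIB-knockdown replicate 1 (0.166). SNAP47 (0.10 ± 0.08), MAP1LC3B (0.14 ± 0.07), SQSTM1 (−0.12 ± 0.04), LAMP1 (−0.13 ± 0.04) and CTSB (−0.13 ± 0.05) did not pass the test. No list call was made for autophagy initiation, with a median of −0.01 (adjusted p = 0.609), or for autophagosome-lysosome fusion, with a median of −0.01 (adjusted p = 0.594).

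Ribosomal protein genes rose by a small shared amount, with a median of 0.07 (0.04 after quantile normalization) and 38 positive values, adjusted p = 1.23e-10, and adjusted p = 0.328 with an estimated correlation. Of 42 measured members 1 rose, and 5 rose adjusted over the list alone. RPS12 rose by 0.18 ± 0.03. Among integrated stress response genes of 28 measured members 1 rose and 1 fell, and 7 rose and 2 fell adjusted over the list alone, with a median of 0.18 (0.10 to 0.20 with 1 library left out), adjusted p = 1.09e-05, and adjusted p = 0.549 with an estimated correlation. The gene that rose over all genes was ASNS, and the gene that fell was SLC7A5, a subunit of a large neutral amino acid transporter (−0.59 ± 0.07). Fatty acid synthesis genes fell, with a median of −0.13, adjusted p = 0.00111, and adjusted p = 0.328 with an estimated correlation. Of 11 measured members 2 fell, and 2 fell adjusted over the list alone. They were the desaturase SCD (−0.26 ± 0.04) and the elongase ELOVL5 (−0.30 ± 0.05).

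NRF2 targets of the oxidative stress response moved down, with a median of −0.08 (−0.11 to −0.01 with 1 library left out), adjusted p = 0.015, and adjusted p = 0.328 with an estimated correlation. Of 18 measured members 2 fell, and 6 fell adjusted over the list alone. The quinone reductase NQO1 (−0.29 ± 0.03) and FTH1, the ferritin heavy chain (−0.27 ± 0.04), fell. The call was lost without detached control replicate 2 (0.122) and detached SPIB-knockdown replicate 1 (0.069), and with no trend (adjusted p = 0.108, range 0.00215 to 0.108). Extracellular matrix genes moved down by a median of −0.12 (−0.14 to −0.06 with 1 library left out), adjusted p = 0.0229, and adjusted p = 0.358 with an estimated correlation. Of 19 measured members none passed the limma test over all genes and 5 did at an unadjusted p under 0.05 (over all 13438 tested genes 1596 did), while 1 fell adjusted over the list alone. That call was lost without detached control replicate 1 (0.147) and detached SPIB-knockdown replicate 2 (0.0779), and with no filter on low values (0.39). Single genes of uncalled lists that changed were HSPA5, the main chaperone of the endoplasmic reticulum (0.23 ± 0.03), the lectin chaperone CANX (−0.26 ± 0.04), HSPB1 (−0.28 ± 0.04) and VCL (−0.35 ± 0.04).

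A short sequence in the 3′ UTR marked many of the genes lowered by the knockdown, a pattern chosen after the values were seen. The words ACCACTA or CCACTAT occur in the 3′ UTR of 42 of the 75 searched genes that fell in detached cells (56.0%) and of 11.4% of 9607 searched genes that were not called. Most of the 1134 searched genes with either word were thus not called. Their median log2 fold change in detached cells was −0.06, against 0.003 for genes with neither word. Of 16305 words scanned, these had the lowest z in attached cells (−9.55 and −9.10) and again in detached cells (−11 and −9.81), which share no library. The largest absolute z in 100 permutations of the attached values was 5.35. GPX4, INA, FAM174A, SAMD4B, IL27RA, LIPA, LAMP2, SLC7A5, ELOVL5 and CANX carry one. NFE2L3, SCD, VCL, NQO1, HSPB1 and FTH1 carry neither there. Among lysosomal genes 5 of 42 searched members carry one, as do 3 of 11 fatty acid synthesis genes. The words with the next lowest z were CACTATA (−5.86 attached, −7.18 detached) and CCACTAA (−5.82, −7.61), also beyond 5.35 in absolute value. They share most of their bases with ACCACTA and CCACTAT. Genes were not sorted by them, so genes said to carry neither word may hold a related one.

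The number of genes called by knockdown in detached cells fell from 99 to 10 and 29 without detached control replicates 1 and 2, to 32 and 33 without detached knockdown replicates 1 and 2, and to 58 and 59 without attached control replicates 1 and 2. GPX4 and INA were the 2 of 29 named calls that held without each of the 8 libraries.

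SPIB knockdown in attached cells, the same question before loss of attachment, again lowered GPX4, which fell from 410 ± 1.31 to 128 ± 2.81 FPKM (SD, n = 2, log2 fold change −1.68 ± 0.03, adjusted p = 1.56e-06). ID2 (−1.34 ± 0.13) and ID1 (−0.96 ± 0.07), inhibitors of basic helix-loop-helix factors, CEBPD, a CCAAT/enhancer binding protein (−1.12 ± 0.15), FAM174A (−1.07 ± 0.09), SAMD11 (−1.16 ± 0.16) and CBY1 (−1.15 ± 0.16) also fell. The genes that rose include HBEGF, a ligand of the EGF receptor, from 29.8 to 59.9 FPKM (0.99 ± 0.08, adjusted p = 0.00309). CDKN1A, the cell cycle inhibitor p21, rose from 23.4 to 46.3 FPKM (0.95 ± 0.07). MMP1 (1.16 ± 0.12), the chemokine CXCL3 (0.93 ± 0.16), PLAUR, the urokinase receptor (0.90 ± 0.10), and ANGPTL4, an inhibitor of lipoprotein lipase (0.85 ± 0.06), rose as well. In total 248 genes changed, 86 higher and 162 lower, of which 5 rose and 7 fell at least 2-fold.

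Immediate early genes, which respond to growth factor signals within minutes, rose in attached knockdown cells, with a median of 0.41 and 20 positive values, adjusted p = 7.28e-10, and adjusted p = 0.328 with an estimated correlation. Of 23 measured members 5 rose, and 15 rose adjusted over the list alone. JUN rose from 29.4 to 49.5 FPKM (0.73 ± 0.05, adjusted p = 0.00309). The zinc finger factor EGR1 rose by 0.85, the phosphatase DUSP5 by 0.71 ± 0.08, and the Sprouty genes SPRY2 by 0.86 ± 0.13 and SPRY4 by 0.61 ± 0.06. NF-kB and inflammatory genes rose, with a median of 0.12 (0.10 to 0.19 with 1 library left out), adjusted p = 0.015, and adjusted p = 0.372 with an estimated correlation. Of 14 measured members 3 rose, and 5 rose and 2 fell adjusted over the list alone, these being MMP1, CXCL3 and the cytokine LIF (0.47 ± 0.06). p53 targets rose, with a median of 0.11, adjusted p = 0.0221, and adjusted p = 0.328 with an estimated correlation. Of 18 measured members 2 rose, and 4 rose adjusted over the list alone, namely CDKN1A and the exonuclease AEN (0.41 ± 0.06). The p53 call was lost without attached SPIB-knockdown replicate 1 (0.115). ELK3 (0.66 ± 0.06) and ETV4 (0.38 ± 0.06), ETS family factors like SPIB, rose, and so did the integrins ITGA6 (0.55 ± 0.05) and ITGA2 (0.60 ± 0.10).

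Lysosomal genes moved down in attached knockdown cells too, with a median of −0.13, adjusted p = 0.00154, and adjusted p = 0.328 with an estimated correlation. Of 43 measured members 1 rose and 4 fell, and 2 rose and 7 fell adjusted over the list alone. LIPA (−0.87 ± 0.10), the galactosylceramidase GALC (−0.80 ± 0.12), the sialic acid exporter SLC17A5 (−0.51 ± 0.09) and LAMP2 (−0.47 ± 0.05) fell, and CTSL rose (0.34 ± 0.04). Among genes of autophagy initiation the receptor CALCOCO2 rose (0.26 ± 0.05), with no list call (median 0.0032, adjusted p = 0.913). SNAP47 (−0.13 ± 0.08), MAP1LC3B (0.19 ± 0.07), SQSTM1 (−0.12 ± 0.04), LAMP1 (−0.08 ± 0.04) and CTSB (−0.12 ± 0.05) did not pass the test. Fatty acid synthesis genes moved down, with a median of −0.15, adjusted p = 0.00306, and adjusted p = 0.328 with an estimated correlation. Of 11 measured members 1 fell, and 4 fell adjusted over the list alone, the call over all genes being SCD (−0.30 ± 0.04). This list's call was lost without attached control replicate 1 (0.0537).

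Integrated stress response genes moved up, with a median of 0.11 (0.07 to 0.17 with 1 library left out), adjusted p = 0.00148, and adjusted p = 0.639 with an estimated correlation. Of 28 measured members 1 rose and 1 fell, and 6 rose and 1 fell adjusted over the list alone. ASNS rose (0.24 ± 0.04) and SLC7A5 fell (−0.51 ± 0.07), and the call was lost without attached control replicate 2 (0.0634). Ribosomal protein genes moved up by a median of 0.07 (0.02 after quantile normalization), adjusted p = 4.69e-07, and adjusted p = 0.358 with an estimated correlation, although of 42 measured members none passed the limma test over all genes and 15 did at an unadjusted p under 0.05 (over all 13438 tested genes 2295 did), nor did any adjusted over the list alone, and quantile normalization ended the call (adjusted p = 0.254, range 2.48e-08 to 0.254). NRF2 targets moved down, with a median of −0.09 (−0.14 to −0.03 with 1 library left out), adjusted p = 0.0313, and adjusted p = 0.355 with an estimated correlation. Of 18 measured members 1 rose and 2 fell, and 1 rose and 7 fell adjusted over the list alone. NQO1 (−0.39 ± 0.03) and FTH1 (−0.25 ± 0.04) fell and the heme oxygenase HMOX1 rose (0.28 ± 0.05), and the call was lost without attached control replicate 2 (0.121), attached SPIB-knockdown replicate 1 (0.051) and attached SPIB-knockdown replicate 2 (0.0684), and with no trend (0.136).

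Respiratory chain genes moved down by a median of −0.05 (−0.08 to −0.03 with 1 library left out), adjusted p = 0.015, and adjusted p = 0.54 with an estimated correlation. Of 28 measured members none passed the limma test over all genes and 6 did at an unadjusted p under 0.05 (over all 13438 tested genes 2295 did), nor did any adjusted over the list alone. This respiratory chain call was lost without attached control replicate 2 (0.168) and attached SPIB-knockdown replicate 1 (0.175), and with no trend (0.0743). Interferon response genes moved down by a median of −0.09 (−0.25 to −0.09 with 1 library left out), adjusted p = 0.0252, and adjusted p = 0.328 with an estimated correlation. Of 22 measured members none passed the limma test over all genes and 6 did at an unadjusted p under 0.05 (over all 13438 tested genes 2295 did), nor did any adjusted over the list alone. Their call was lost without attached control replicate 2 (0.0858) and attached SPIB-knockdown replicate 1 (0.131), and with no filter on low values (0.203) and a filter at 5 FPKM (0.29). Other called members of lists include HSPB1 (−0.49 ± 0.04), HSPA8 (0.31 ± 0.03), the filamin FLNA (−0.22 ± 0.04), BHLHE40 (0.54 ± 0.06), CTGF (0.41 ± 0.05) and SEL1L, a component of protein quality control in the endoplasmic reticulum (−0.86 ± 0.14). CITED2 (−0.21) fell and the integrin ITGB5 (0.24) rose as well.

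The 3′ UTR words ACCACTA or CCACTAT occur in 54 of the 134 searched genes that fell in attached cells (40.3%), against 11.3% of 9484 searched genes that were not called and 5 of 70 that rose. The words were picked by their z in these same attached libraries, so this excess follows from the choice and is no test of it. GPX4, FAM174A, CEBPD, LIPA, LAMP2, GALC, SLC7A5 and SEL1L carry one, and ID1, ID2, SAMD11, CBY1, SLC17A5, SCD, FLNA, NQO1, HSPB1 and FTH1 carry neither. The number of genes called in attached cells was 38 and 42 without attached control replicates 1 and 2, 77 and 72 without attached knockdown replicates 1 and 2, 114 and 118 without detached control replicates 1 and 2, and 143 without either detached knockdown replicate. Of 51 named calls, 11 held without each of the 8 libraries: GPX4, ID1, FAM174A, HSPB1, NQO1, HBEGF, CDKN1A, ANGPTL4, JUN, ELK3 and ITGA6.

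**Figure D3:**
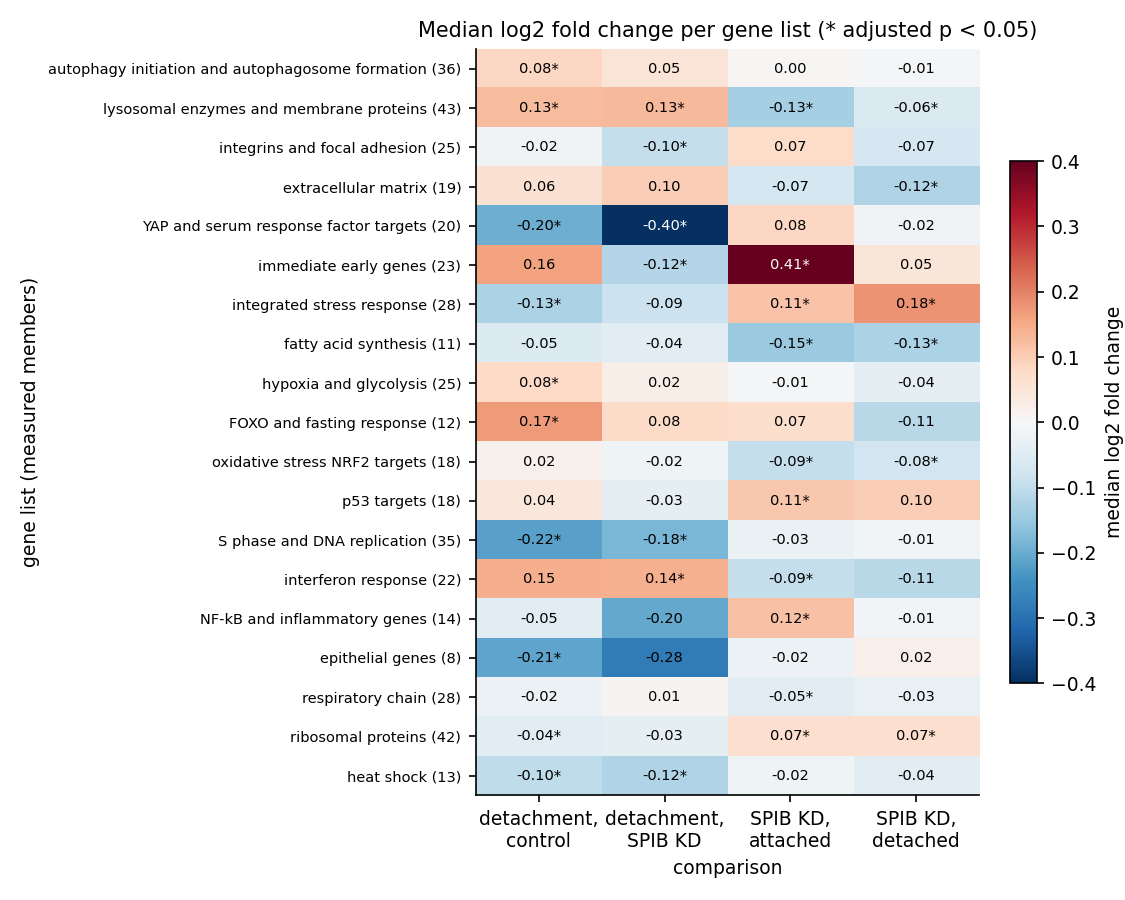
Median log2 fold change (colour, and the value in each cell) of 19 gene lists (y axis, with the number of measured members) in the 4 pairwise comparisons (x axis). An asterisk marks an adjusted p under 0.05 by camera with a preset correlation. YAP and serum response factor targets have the lowest median, −0.40, for detachment in knockdown cells, and immediate early genes the highest, 0.41, for knockdown in attached cells.

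Detachment of SPIB-knockdown cells lowered much the same leading genes as detachment of control cells. CTGF fell from 95.2 to 25 FPKM (log2 fold change −1.88 ± 0.05, adjusted p = 2.21e-05). IGFBP3 fell from 125 ± 14.6 to 14.5 ± 2.59 FPKM (SD, n = 2, −3.02 ± 0.19) and CYR61 fell as well (−1.86 ± 0.08). CALD1, the actin and myosin binding protein caldesmon, fell from 40.5 to 12.5 FPKM (−1.62 ± 0.08, adjusted p = 0.000258). KRTAP2-3 (−2.46 ± 0.13) and its near copy KRTAP2-4 (−1.77 ± 0.31) fell with the same uncertainty. KRTAP2-4 lay at only 0.877 and 1.36 FPKM in the detached knockdown libraries. MMP1 rose from 8.92 to 22.6 FPKM (1.25 ± 0.12, adjusted p = 0.00249), as did the galactosyltransferase gene B3GALT4 (1.43 ± 0.26), HIST1H2BJ, a histone gene with near-identical copies and so uncertain (1.18 ± 0.25), KLHL24 (1.10 ± 0.17) and NDRG2 (1.10 ± 0.19). Of 956 genes called, 276 were higher and 680 lower, 19 and 38 of them at least 2-fold. After quantile normalization 334 were higher and 350 lower, and after rescaling without small RNA, rRNA and mitochondrial genes 399 and 402.

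YAP and serum response factor targets fell in knockdown cells, with a median of −0.40, adjusted p = 3.84e-09, and adjusted p = 0.328 with an estimated correlation. Of 20 measured members 11 fell, and 12 fell adjusted over the list alone. Examples are AMOTL2 (−1.45 ± 0.11) and CRIM1 (−0.82 ± 0.07). S phase genes moved down, with a median of −0.18, adjusted p = 8.98e-06, and adjusted p = 0.482 with an estimated correlation. Of 35 measured members 5 fell, and 8 fell adjusted over the list alone. RRM2 (−0.32 ± 0.05), TYMS (−0.23 ± 0.04), the helicase subunit MCM7 (−0.19 ± 0.04) and the phosphatase CDC25A (−0.54 ± 0.11) fell. Among integrins and focal adhesion genes of 25 measured members 5 fell, and 6 fell adjusted over the list alone, with a median of −0.10 (−0.02 after quantile normalization and −0.04 after rescaling), adjusted p = 0.0229, and adjusted p = 0.328 with an estimated correlation. ITGA6 (−0.70 ± 0.05), caveolin CAV1 (−0.52 ± 0.04), ITGB5 (−0.37 ± 0.04) and alpha-actinin ACTN1 (−0.37 ± 0.04) fell, and the list's call was lost without attached SPIB-knockdown replicate 1 (0.0746) and with a filter at 5 FPKM (0.0501), quantile normalization (0.359) and no trend (0.0602).

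Lysosomal genes rose, with a median of 0.13 and 32 positive values, adjusted p = 2.32e-05, and adjusted p = 0.328 with an estimated correlation. Of 43 measured members 7 rose and 1 fell, and 13 rose and 1 fell adjusted over the list alone. CTSL (0.51 ± 0.04), SLC17A5 (0.53 ± 0.09), LIPA (0.54 ± 0.10), CTSB (0.33 ± 0.05), LAMP2 (0.24 ± 0.05), PSAP (0.21 ± 0.03) and TFEB, a transcription factor of lysosomal genes (0.52 ± 0.10), rose, and the protease gene CTSC fell (−0.32 ± 0.08). SQSTM1 rose (0.28 ± 0.04), while EPG5, a tether for autophagosomes and lysosomes (−0.86 ± 0.13), the SNARE gene YKT6 (−0.20 ± 0.04) and ATG4B, the protease that processes LC3 (−0.34 ± 0.06), fell. Neither list passed its test: in autophagosome-lysosome fusion 2 of 24 rose and 3 fell, LOH12CR1 (0.52 ± 0.10) and LAMP2 being higher (adjusted p = 0.851), and in autophagy initiation 1 of 36 rose and 2 fell (adjusted p = 0.186). SNAP47 (0.11 ± 0.08), MAP1LC3B (0.03 ± 0.07) and LAMP1, whose value of −0.06 turns positive after quantile normalization, did not pass the test.

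Immediate early genes moved down by detachment of knockdown cells, with a median of −0.12 (−0.28 to −0.08 with 1 library left out and −0.07 after rescaling), adjusted p = 0.0252, and adjusted p = 0.6 with an estimated correlation. Of 23 measured members 6 fell, and 1 rose and 8 fell adjusted over the list alone. DUSP5 (−0.96 ± 0.08), DUSP1 (−0.70 ± 0.10), MYC (−0.68 ± 0.06) and JUN (−0.65 ± 0.05) fell, and the call was lost without attached SPIB-knockdown replicate 1 (0.051) and detached SPIB-knockdown replicate 2 (0.145). Interferon response genes rose, with a median of 0.14, adjusted p = 0.0147, and adjusted p = 0.328 with an estimated correlation. Of 22 measured members 2 rose, and 2 rose adjusted over the list alone, these being STAT2 (0.65 ± 0.11) and PARP14 (0.41 ± 0.09). That call was lost without attached SPIB-knockdown replicate 1 (0.0657), and with a filter at 5 FPKM (0.0953) and quantile normalization (0.085). Heat shock genes moved down by a median of −0.12 (−0.05 after quantile normalization and −0.06 after rescaling), adjusted p = 0.0447, and adjusted p = 0.654 with an estimated correlation. Of 13 measured members 1 rose and 3 fell, and 1 rose and 5 fell adjusted over the list alone, with HSPA8 (−0.33 ± 0.03) and HSPD1 (−0.28 ± 0.04) lower and HSPB1 higher (0.25 ± 0.04). The heat shock call was lost without attached control replicate 1 (0.0569), attached control replicate 2 (0.0618), attached SPIB-knockdown replicate 1 (0.107), attached SPIB-knockdown replicate 2 (0.0525), detached control replicate 2 (0.0566) and detached SPIB-knockdown replicate 2 (0.176), and with a filter at 5 FPKM (0.0862), median of ratios scaling (0.0679), quantile normalization (0.522), rescaling (0.0992) and no trend (0.17). Of cell death genes, the caspase gene CASP9 rose (0.91 ± 0.16), and cytochrome c, CYCS (−0.35 ± 0.04), and the inhibitors of apoptosis BIRC2 (−0.50 ± 0.09) and BIRC3 (−0.50 ± 0.10) fell.

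The number of genes called by detachment in knockdown cells moved from 956 to 288 and 243 without attached knockdown replicates 1 and 2, and to 297 and 150 without detached knockdown replicates 1 and 2. Of 88 named calls 28 held without each of the 8 libraries, among them IGFBP3, CTGF, CYR61, CALD1, KRTAP2-3, CCL2, AMOTL2, GADD45A, DUSP5, ITGA6, MYC, JUN, ANGPTL4, MMP1 and CTSL.

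**Figure D4:**
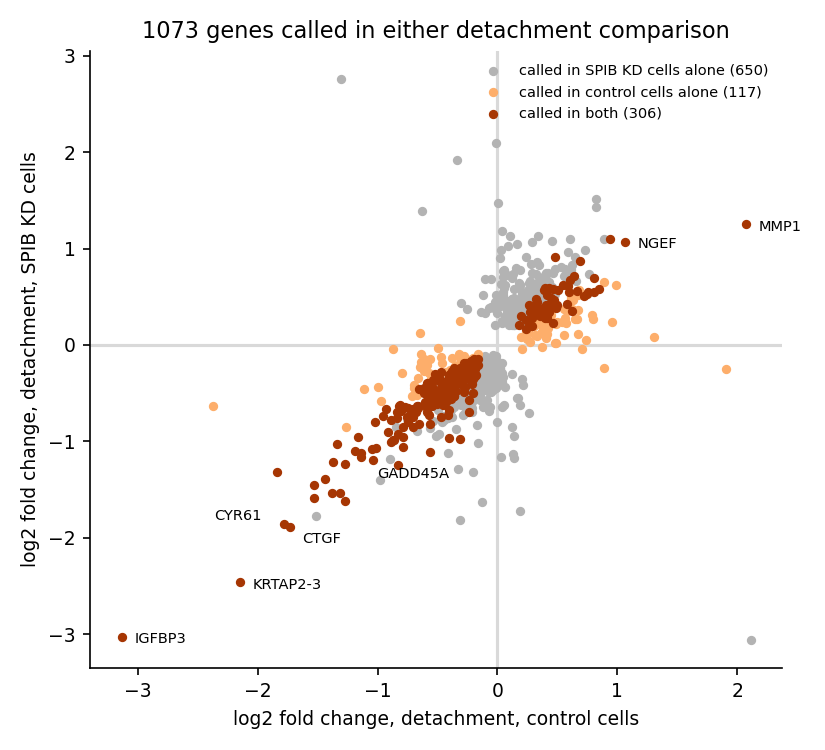
Log2 fold change by detachment in control cells (x axis) and in SPIB-knockdown cells (y axis) of the 1073 genes called in either, coloured by whether they were called in both (306), in control cells alone (117) or in knockdown cells alone (650). Most points lie in the quadrants where both values have the same sign.

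Of the 423 genes called by detachment in control cells, 416 had the same sign in knockdown cells, and the fold changes of all 13438 genes correlated with r = 0.419 across genes. These comparisons share no library. Both called 245 genes lower, where independent lists would share 15.3, and 61 higher, where they would share 2.47. They use the same spread per gene, so their calls are not independent and this baseline can be too low. The interaction itself, which asks whether the knockdown effect differed between the attached and the detached state, called 0 genes by limma, with 898 genes at an unadjusted p under 0.05. The smallest adjusted p was 0.214, for ANGPTL4 (−0.81 ± 0.08), and the next genes were TFPI2 (−0.67), JUN (−0.58) and ITGA6 (−0.46), each with an adjusted p of 0.375. Without attached knockdown replicate 1, the interaction called 3 genes. It called 1 gene each without attached knockdown replicate 2, attached control replicate 1 or 2, or detached control replicate 2.

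**Figure D5:**
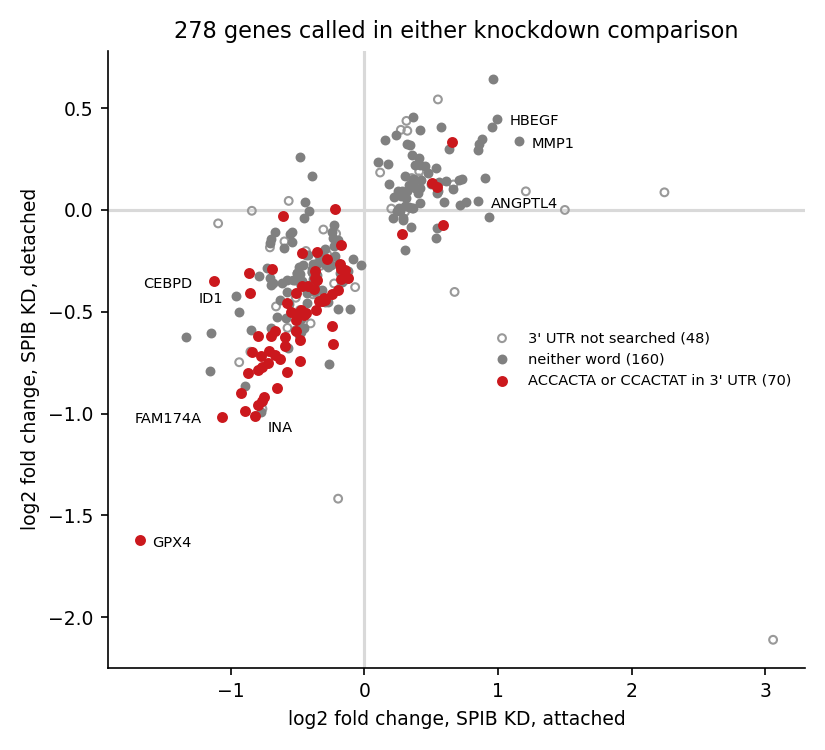
Log2 fold change by SPIB knockdown in attached (x axis) and detached cells (y axis) of the 278 genes called in either, with 70 genes that carry ACCACTA or CCACTAT in the 3′ UTR in red, 160 that carry neither in grey and 48 that were not searched as open circles. GPX4 lies lowest of the labelled genes on both axes.

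Genes called by the knockdown mostly had the same direction in both states. All 99 genes called in detached cells had the same sign in attached cells, as had 227 of the 248 called in attached cells, and the correlation over all genes was r = 0.227 across genes, with no library shared. This correlation was 0.12 with a pseudocount of 0.1, 0.15 with no filter on low values and 0.31 with a filter at 5 FPKM. Both knockdown comparisons called 63 genes lower, where independent lists would share 1.07, and 6 higher, where they would share 0.064. As for detachment, the shared spread per gene means that this baseline can be too low. Beside GPX4 and FAM174A, the genes lowered in both include RMDN3 (−0.92 attached, −0.90 detached), the deubiquitinase USP46 (−0.90, −0.99), TMED2, a cargo receptor of the early secretory pathway (−0.78, −0.72), and SEPT2, a septin (−0.65, −0.87). The NOMO1, NOMO2 and NOMO3 copies also fell in both and cannot be told apart with certainty. A word occurs in 31 of the 52 searched genes called lower in both (59.6%), a share that rests in part on the attached libraries from which the words were picked.

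Whether genes moved by detachment were moved back by the knockdown was asked in the detached state. The fold changes by detachment in control cells and by knockdown in detached cells correlated with r = −0.314 across genes, where simulated unchanged groups give −0.495 (SD 0.104) because both comparisons use the detached control libraries with opposite sign. The covariance was −0.0193, against −0.03 in the simulation, a difference of 0.0107. The simulation drew on the spread of every tested locus, including the 21 listed at 0 in a library and at 10 FPKM or more in another. Such loci, a mitochondrial one among them, vary widely within groups, and the simulation was not repeated without them. Without them the observed r was −0.329. The distance from the simulated values therefore cannot show whether the knockdown moved genes back. Among called genes 6 rose by detachment and fell by knockdown, where independent lists would share 0.795, and 2 fell and then rose, where they would share 0.226. CD9, a tetraspanin (0.25, −0.61), COL18A1 (0.26, −0.59), the collagen receptor DDR1 (0.47, −0.27) and VCL belong to the first kind, with the locus merging VWA1 and ATAD3C and RP11-490M8.1, which is listed at or near 0 in 3 groups. CLDN1 and SNHG5 belong to the second. Another 4, INA, ENAH, PTRF and the locus that holds ADAM9, fell in both, where independent lists would share 2.01. Part of the overlaps in opposite directions can come from the shared detached control libraries, which enter with opposite sign. These libraries were not split, since a split would leave 1 of them on each side.

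Of the 32 lists, 12 had no call in any contrast. Their smallest adjusted p was 0.0682 for replication-dependent histones, 0.138 for ETS family factors, 0.22 for mesenchymal genes, 0.255 for vacuolar ATPase subunits and for pro-survival genes, 0.311 for pro-apoptotic genes, 0.469 for cholesterol synthesis, 0.518 for endoplasmic reticulum chaperones and 0.594 for autophagosome-lysosome fusion. It was 0.7 for squamous and lung lineage genes, of which only 6 of 29 were measured. Markers of other cell types likewise had no call, with 0.224 for lymphoid and myeloid markers, of which 6 of 29 were measured, and 0.432 for fibroblast and endothelial markers, of which 3 of 17 were measured. Median, mean and test had the same sign in each of the 38 list calls. They differed in sign among uncalled tests, as for autophagosome-lysosome fusion by knockdown in attached cells, with a median of 0.03, a mean of −0.02 and a downward test.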

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

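The contrast and the lists below were fixed before the data were examined, and the tests that weigh explanations here were chosen after the result was seen. Immediate early genes rose by the SPIB knockdown in attached cells (median 0.41), with no call in detached cells. There the median was 0.05, or 0.04 to 0.12 with 1 library left out, with 16 of 23 members positive (adjusted p = 0.311). The difference between the responses, detached minus attached, had a median of −0.34 over 23 members (adjusted p = 7.28e-10, and adjusted p = 0.328 with an estimated correlation). JUN, a subunit of AP-1, differed by −0.58 ± 0.08, and 4 members were lower adjusted over the list alone, while limma called 0 of them over all genes, where 898 genes had an unadjusted p under 0.05. Integrin and focal adhesion genes differed by a median of −0.15, which ranged from −0.18 to −0.10 with 1 library left out (adjusted p = 6.9e-05, and adjusted p = 0.328 with an estimated correlation), with ITGA6, a laminin receptor subunit, at −0.46 ± 0.06 and 4 members lower adjusted over the list alone.

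NF-kB and inflammatory genes differed by a median of −0.17, or −0.11 after rescaling (adjusted p = 0.00611, and adjusted p = 0.356 with an estimated correlation), with 3 members lower adjusted over the list alone. YAP and serum response factor targets differed by a median of −0.0799 (adjusted p = 0.0147, and adjusted p = 0.356 with an estimated correlation), a call lost without attached control replicate 2 (0.0601), attached SPIB-knockdown replicate 1 (0.0751), detached control replicate 1 (0.0835) and detached SPIB-knockdown replicate 2 (0.0572), after quantile normalization (0.0596) and with no trend (0.0609). Mitosis genes differed by a median of 0.0548, which ranged from 0.0217 to 0.0964 with 1 library left out and was 0.0874 after quantile normalization (adjusted p = 0.0161, and adjusted p = 0.639 with an estimated correlation), a call lost without attached control replicate 1 (0.0726), attached SPIB-knockdown replicate 2 (0.0727), detached control replicate 2 (0.254) and detached SPIB-knockdown replicate 1 (0.233) and with no trend (0.0672).

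The mean log2 level of the immediate early genes was 4.21 and 4.16 in the attached knockdown libraries and 3.81 and 3.77 in the attached control libraries. A single library does not account for the difference, since the median nearest to 0 with a library left out was −0.28. The smallest gap between an attached knockdown and an attached control library was 0.35 (−0.0067 among detached ones). This gap may come from the knockdown or from how the cultures of either attached group were handled. Handling of the detached groups may also bear on the difference between the responses. Both libraries of a group share its handling, so these data cannot separate handling from the knockdown. Attached knockdown cultures harvested again on other days, next to attached controls, would.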

How the results depend on the processing

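Of the settings here, leaving out 2 kinds of loci and leaving out libraries for the gene lists were chosen after the result was seen. With no filter on low values, more genes enter both the fit and the adjustment. Calls were then 190 for detachment in control cells and 61 and 110 for knockdown in detached and attached cells. They were 476 for detachment in knockdown cells. In the same order they were 56, 6, 28 and 188 with only the 4 samples compared, where fewer samples estimate the spread. With no intensity trend they were 120, 26, 66 and 348. The causes of these lower counts were not tested.

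With 1 library left out, calls ranged from 56 to 270 for detachment in control cells, 10 to 69 and 38 to 143 for knockdown in detached and attached cells, 150 to 723 for detachment in knockdown cells and 0 to 3 for the interaction. The locus that holds SPIB ranged from −0.17 to −0.03 by knockdown in attached and −0.21 to −0.06 in detached cells. The correlation across genes of detachment with knockdown ranged from −0.55 to −0.23, that of both knockdown responses from 0.15 to 0.22, and the number of list calls from 27 to 37. With the replicate number as a block, whose numbers pair libraries weakly at most by their values (correlations −0.02 to 0.12 over all genes and 0.03 to 0.36 over abundant ones), calls were 334, 70, 198, 903 and 0, with 38 list calls, which lack epithelial genes by detachment in control cells and NRF2 targets by knockdown in attached cells.

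Of 7890 repeated results for named genes, 6519 stayed the same, 1274 were weaker, 70 stronger and 27 reversed. All that reversed lay near 0. A result that was not called and stayed so counts as the same, so these totals understate the share of calls that were lost. With all libraries kept, 18 of 51 named calls by detachment in control cells held under every alternative. For knockdown 2 of 29 held in detached and 9 of 51 in attached cells, and for detachment in knockdown cells 28 of 88. LAMP1 by detachment in control cells turned to 0.0067 after median of ratios scaling, 0.0377 after quantile normalization and 0.0329 after rescaling. By detachment in knockdown cells, quantile normalization turned RPS14 to 0.0347, RPLP1 to 0.00033, LAMP1 to 0.0377, the SNORD78 and GAS5 locus to 0.0542 and ZFAS1 to 0.00301. For the interaction it turned CTSB to 0.0089 and LAMP1 to 0.000046. Rescaling turned CTSB to 0.0046 and SQSTM1 to 0.0090, and median of ratios scaling turned SQSTM1 to 0.0011. With 1 library left out, MAP1LC3B ranged from −0.0539 to 0.112 by detachment in knockdown cells and LAMP1 from −0.0475 to 0.0323 by detachment in control cells. For the interaction MAP1LC3B ranged from −0.13 to 0.0364, CTSB from −0.0676 to 0.0428, SQSTM1 from −0.043 to 0.0268 and the locus that holds SPIB from −0.109 to 0.0385.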

Other observations

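The tests in this part were all chosen after the result was seen. Host genes of small nucleolar RNAs, whose introns carry these RNAs, were mostly higher by knockdown and lower by detachment. Of 13 such genes, 10 were higher by knockdown in attached cells, 4 of them called, with a median of 0.20. In detached cells 9 were higher, 4 of them called, with a median of 0.21. ZFAS1 rose by 0.31 ± 0.06 and 0.44 ± 0.06, SNHG5 by 0.32 ± 0.05 and 0.39 ± 0.05, and C6orf48 by 0.31 ± 0.04 and 0.32 ± 0.04. The locus of SNORD78 and GAS5, a merged one, rose by 0.27 ± 0.05 and 0.39 ± 0.05. By detachment 11 of the 13 were lower in control cells, 3 of them called, with a median of −0.17. In knockdown cells 12 were lower, 3 of them called, with a median of −0.19. In detached cells SNHG9 (−1.09) and SNHG7 (−0.73) lay the other way by more than any host rose, and neither passed the test. The list was put together after some of these genes were seen to rise, so no test of it is given.

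Among genes lowered by the knockdown, such as GPX4, short 3′ UTR words recur. In a model with 3′ UTR length, base composition and expression, ACCACTA had a z of −11 in detached cells. The largest absolute z in 100 permutations of the attached values was 5.35, and no permutations were run for detached cells. These properties, as modelled, do not account for the z. The percentage of carriers among genes lowered in detached cells, 56, is what direct pairing of the knockdown reagent with these mRNAs could leave. The joined word ACCACTAT lies in the 3′ UTR of the SPIB transcript SPIB-201 (bases 1061 to 1068, GRCh38 chromosome 19, 50428607 to 50428614). SPIB-202 and SPIB-205 hold it too, while SPIB-206 and SPIB-207 lack it. The coding or 3′ UTR sequence of 3.33% of coding genes holds the joined word. For the 33 lowered genes with neither word in the 3′ UTR, lower SPIB activity may be the cause, which cannot be judged while SPIB lies in a merged locus. These 33 were not checked for CACTATA or CCACTAA, related words whose z also lay beyond 5.35 in absolute value. Pairing is not excluded for the 33, since 6 of them carry ACCACTA or CCACTAT in the coding sequence (18.2% against 10.1% of genes not called, Fisher's exact p = 0.14). In attached cells 18 of 80 do (22.5%, against 842 of 8409 genes not called, Fisher's exact p = 0.00106). These tests take no account of coding length, base composition or expression, so an excess need not come from pairing. A second reagent against another part of SPIB, or SPIB without the ACCACTAT site put back, would separate pairing from lower SPIB activity.

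A mitochondrial locus was listed at 0 in attached control replicate 1, attached knockdown replicate 2, detached control replicate 1 and detached knockdown replicate 1, and between 47540 and 47980 FPKM in the other libraries. These 4 are the deepest libraries by the ratio of low values, which 1 of 70 arrangements gives (exact p = 0.0143). With 1 library at 0 held fixed in each group, fewer arrangements are possible and the p would be larger. An estimate that failed at high depth is therefore possible but not settled. A difference between groups is ruled out, since each of the 4 groups has 1 library at 0. Counting the reads of this locus again would settle it.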
